A study of Homo sapiens with 4 samples.

How the data were processed

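RNA was measured in LNCaP cells, an androgen-sensitive human prostate cancer cell line, on 4 Affymetrix expression arrays, 1 array for each combination of siRNA (siControl or siPOTEF-AS1) and hormone (vehicle or dihydrotestosterone, DHT). Per the labels' protocols, cells were grown in medium with 10% fetal bovine serum, kept for 3 days in phenol red-free medium with 2.5% charcoal-stripped serum, transfected 48 h before the hormone was added, and treated with ethanol vehicle or 10 nM DHT. Total RNA was extracted with ISOGEN and labelled with the Affymetrix whole transcript terminal labelling kit, per the labels' protocols. The duration of the hormone treatment is not given in the sources used here.

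The values deposited by the authors are log2 signals per probe set, made with Affymetrix Expression Console and RMA per the submitters' processing notes, with no versions named there. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a probe set on the log2 scale. It therefore removes any change in the total amount of RNA per cell, and its background model compresses the differences of dim probe sets. The same values were deposited in a second table, where they differed from the first by at most 1.78e-15. The 4 array medians lay between 6.72 and 6.77 and the upper quartiles between 8.74 and 8.80. No detection call or scanner intensity was used here, so that signal over background was not known for single probe sets, and the number of arrays limits the precision.

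Of 33297 probe sets, 26722 carried an annotated transcript and 6575 did not. The table paired 2540 probe sets with 1 gene symbol and 55 with several, which were left unnamed. Another 156 were named through their RefSeq accession in the RefSeq gene table of assembly GRCh38.p14, used for names alone. A further 19068 probe sets were annotated only by a UCSC transcript identifier that the tables used here did not pair with a gene. Named probe sets were thus 10.1% of the annotated ones, and most genes of well known pathways are not analysed here by name. Symbols are those of the table unless a current symbol is given. Coordinates are those the table gives for Ensembl transcripts, on GRCh37.

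Each gene was represented by its probe set with the highest mean over the 4 arrays, which left 2548 named genes. A gene counted as expressed if its highest value reached the median of all values of named genes, a log2 signal of 6.50. Of the named genes, 1344 did. The counts and correlations were repeated on annotated probe sets whatever their name. Probe sets with identical values on the 4 arrays were counted as 1 there, leaving 26187, of which 13747 passed the same filter at their own median of 6.82. This second set was chosen after seeing the data, because so few probe sets carried a name.

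With 1 array per group no single comparison of 2 arrays could be tested, and the difference of the DHT responses left no residual degree of freedom. Differences are log2 differences between 2 arrays, and a gene counted as higher or lower at 2-fold or more. The DHT difference was measured in both siRNA arms and the knockdown difference in both hormone treatments. The arrays of one such pair are not those of the other, so their likeness was used as the repeat measurement of the design. The error of a mean over both arms is given as the distance of either arm from that mean. It holds noise and any true difference between the arms together. Genes are not independent replicates, and the 95% intervals of correlations, from 1000 bootstrap draws of genes, describe these arrays only. A test over all 4 arrays was added after seeing the data: a linear model of siRNA and hormone was fitted with limma to the expressed named genes and, apart from these, to the expressed annotated probe sets, with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. It has 1 residual degree of freedom per gene and assumes that DHT has the same effect in both siRNA arms, so it cannot test whether the effects differ.

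Gene lists were fixed before the data were examined, 28 in all with 541 different genes. Of these genes, 37 were measured under their name. A list with at least 3 measured genes was described by its median log2 difference and by the percentile of that median among 10000 random lists of the same size drawn from the same 20 classes of mean signal. It was called shifted when the median lay outside the central 95% of the random lists. Of the 28 lists, 5 had 3 or more measured genes, 11 had 1 or 2, and 12 had none.

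The genes named in the text follow a rule fixed before the data were examined. For DHT these are up to 12 genes in each direction with the largest mean difference among expressed genes at least 2-fold apart the same way in both siRNA arms. The same rule was applied to knockdown over both hormone treatments, at 1.5-fold where fewer than 5 genes qualified. For the difference between the DHT responses the rule took up to 10 genes in each direction at 2-fold or more. It added each measured POTE gene and up to 4 expressed members of each list. Other genes are marked as chosen after their values were seen.

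The counting was tested on simulated arrays made from the mean signals of the named genes with noise drawn from the residuals of the data, with 1344 expressed genes and 50 changed genes at each fold. In the DHT comparison of 1 pair, 2% of genes changed by 1.5-fold were called, 54% of those changed by 2-fold, and 100% of those changed by 3-fold or 4-fold. Both pairs called 20% of the genes changed by 2-fold, and no unchanged gene was called. The linear model called 49 of 50 genes changed by 1.5-fold, 50 of 50 at each larger fold and 9 of 1144 unchanged genes for DHT, and no gene for knockdown, for which none had been changed. All simulated genes drew their noise from 1 pool, and many genes were changed, both of which make calls by the linear model easier. Its rates here therefore do not give its power for knockdown in the data. In the simulated knockdown comparison, 75% of 100 lists of 6 genes shifted by 0.2 on the log2 scale lay outside the central range, against 8% of unchanged lists. Alternatives to the brightness filter, the scaling, the choice of probe set, the threshold and the drawing of random lists were tried. The analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. No array was left out in turn, since leaving out 1 array removes a whole group and leaves the linear model no residual degree of freedom. A measured member of the fixed lists is not reported here.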

Results

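Gene expression was profiled in LNCaP prostate cancer cells on 4 arrays that formed 4 groups of 1 array each. Cells received a control siRNA or an siRNA against POTEF-AS1, an antisense long noncoding RNA of the POTEF locus, and were then treated with vehicle or with 10 nM DHT, the potent natural androgen. The design asked which androgen-dependent expression changes followed the knockdown. The arrays were closely alike, with Pearson correlations over all 33297 probe sets from 0.988 to 0.995. The highest correlation was that between both DHT arrays and the next highest, 0.994, that between both vehicle arrays, so that hormone separated the arrays more than siRNA did. No group had a second array, so that each value below is that of a single array, and a difference was set against the same difference in the other arm.

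The targeted transcript was examined first. None of the 33297 probe sets carried the symbol or a RefSeq accession of POTEF-AS1, so its level is not analysed here and the knockdown itself was not checked. The POTE family, a group of near-identical primate-specific ankyrin repeat genes expressed in prostate, was represented by 6 probe sets, of which 1 carried the symbols of both POTEB2 and POTEB. POTEF (ENSG00000196604; chromosome 2, 130832909 to 130878140, minus strand, GRCh37) had log2 signals of 6.30 in siControl vehicle cells, 7.72 in siControl DHT cells, 6.64 in siPOTEF-AS1 vehicle cells and 8.23 in siPOTEF-AS1 DHT cells. It was thus 1.42 higher with DHT on the log2 scale in siControl cells and 1.59 higher in siPOTEF-AS1 cells. With knockdown POTEF was not lower but higher, by 0.34 on the log2 scale in vehicle and by 0.51 in DHT, both below the 2-fold threshold. POTEG was 1.07 higher with DHT in siControl cells and 1.46 higher in siPOTEF-AS1 cells. Its signal was 5.9 on each vehicle array, below the brightness floor. POTEJ differed by 0.10 and 0.37. The probe sets of POTEI disagreed. The brighter, with a signal of 12.72 in siControl vehicle cells, differed by -0.03 and -0.11 with DHT, and the dimmer by 1.21 and 1.56, with signals within 0.2 of those of POTEF on each array. In siControl vehicle cells the dimmer, at 6.48, and POTEF were below the floor too. Probes of such near-identical copies may read each other's transcripts, and the values of single POTE genes are uncertain for that reason. The median of the 4 measured POTE genes was 0.34 higher with knockdown in DHT, at the 99.95th percentile of matched random lists, and 0.02 higher in vehicle, at the 68.3rd percentile. With arrays centred on their medians these medians were 0.29 and 0.09, and with the intensity trend removed 0.34 and 0.07. The random lists were matched on signal, not on DHT response or likeness of sequence, so the percentiles may overstate how unusual the list was. With knockdown in DHT, POTEF stood at the 99.2nd percentile of expressed annotated probe sets but at the 94.1st of the DHT-induced ones.

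**Figure D1:**
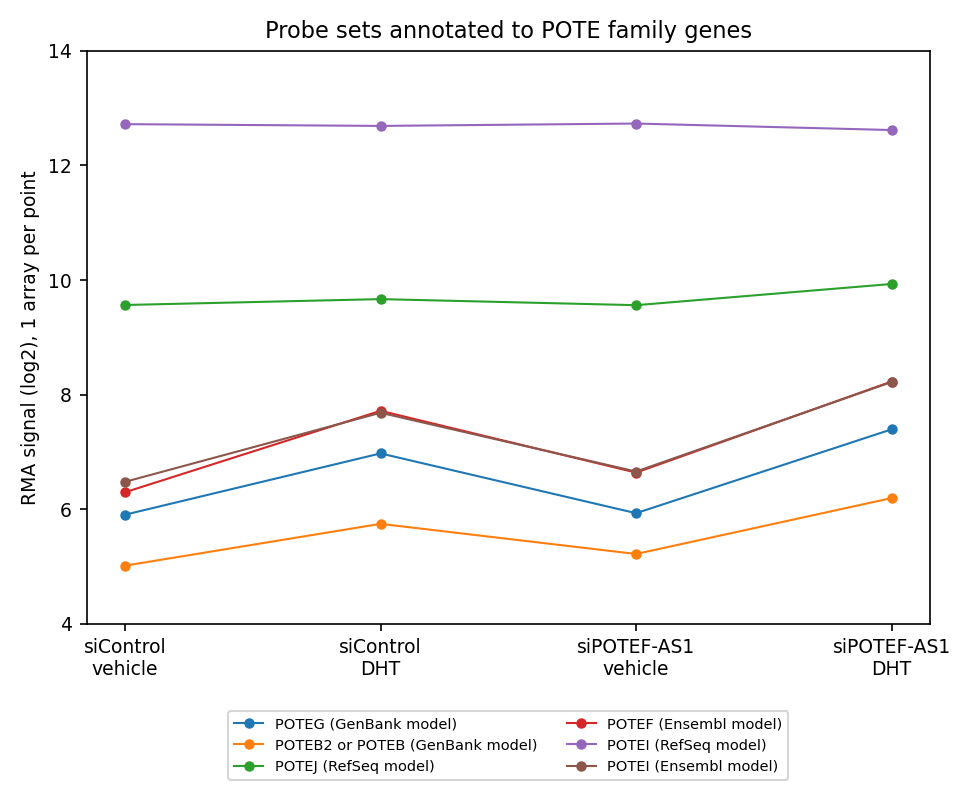
Log2 signal of the 6 probe sets annotated to POTE genes, 1 point per array, joined by lines for each probe set, with the 4 groups along the horizontal axis. The POTEF, POTEG, POTEB2 or POTEB and dimmer POTEI probe sets were higher on both DHT arrays, POTEF at 7.72 and 8.23 against 6.30 and 6.64, while the brighter POTEI probe set stayed near 12.7; the lines of POTEF and the dimmer POTEI nearly coincide.

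The response to DHT was large and alike in both siRNA arms. In siControl cells 17 of 1344 expressed named genes were at least 2-fold higher with DHT and 9 were lower. In siPOTEF-AS1 cells 15 were higher and 12 lower. At 1.5-fold the splits were 38 higher and 41 lower, and 49 and 54. Both arms shared 13 of the higher genes and 7 of the lower genes, against 0.19 and 0.08 for independent lists, and no gene was 2-fold apart in opposite directions. The genes with the largest mean difference were ST6GALNAC1, which encodes a sialyltransferase of O-linked glycans, and SGK1, the serum- and glucocorticoid-regulated kinase. ST6GALNAC1 was higher by 3.55 ± 0.34 on the log2 scale and SGK1 (chromosome 6, 134490384 to 134639196, minus strand, GRCh37) by 3.13 ± 0.24, as the mean of 2 arms and the distance of either arm from it. CENPN, a centromere protein gene, was 6.43-fold higher and TARP, a transcript of the T cell receptor gamma locus expressed in prostate, was 6.23-fold higher. The growth factor receptor gene IGF1R was higher by 2.48 ± 0.08, or 5.56-fold, and AGR2, which encodes an endoplasmic reticulum protein of the disulfide isomerase family, by 2.35 ± 0.35. MICAL1, an actin-oxidising monooxygenase gene, was 4.02-fold higher and LRIG1, a negative regulator of receptor tyrosine kinases, 3.29-fold. POTEF, at 1.51 on the log2 scale, the transcriptional regulators ID2 and ZBTB16, and the orphan nuclear receptor gene NR4A1, the latter 3 at 2.42-fold to 2.53-fold, completed the 12 named genes. The error of ID2, 0.30 on a mean of 1.34, was the largest relative to its mean among these 12. ST6GALNAC1, SGK1 and AGR2 in both arms, and POTEF in siControl cells, lay below the brightness floor in vehicle, a level not shown to be above background, so no fold is given for them.

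The genes lower with DHT in both arms were led by COLEC12, a scavenger receptor gene (ENSG00000158270; chromosome 18, 319361 to 500722, minus strand, GRCh37). Its log2 signal was 9.81 and 9.76 on the vehicle arrays and 7.84 and 7.85 on the DHT arrays, a mean difference of -1.94 ± 0.03, or 3.84-fold. EFCAB11 was 2.21-fold lower. The other 5 of the 7 genes lay below the floor with DHT in at least 1 arm, so that no fold is given for them either. TNFSF18, the gene of a tumour necrosis factor family ligand, differed by -2.04 and -1.22 on the log2 scale. The mean difference was -1.48 for MCTP1, -1.46 for RFX3, a transcription factor gene of ciliated cells, -1.26 for the pseudogene ANKRD20A9P and -1.11 for C10orf91, whose current symbol is LINC02870. A linear model of siRNA and hormone over the 4 arrays, added after seeing the data and assuming the same DHT effect in both arms, gave each of the 19 named DHT-responsive genes a limma adjusted p between 0.00026 and 0.00825. Past an adjusted p of 0.05 it called 51 of the 1344 genes higher and 61 lower, of which 24 were 2-fold apart. Over the 1344 expressed named genes the DHT differences of both arms correlated with r = 0.76 (95% interval 0.70 to 0.81) and a Spearman rho of 0.53. Over the 13747 expressed annotated probe sets r was 0.80. Of these, 223 were higher and 92 lower with DHT in siControl cells, and 205 higher and 159 lower in siPOTEF-AS1 cells. The latter split became 183 and 196 with arrays centred on their medians, and 553 and 742 at 1.5-fold. Both arms shared 168 higher and 62 lower probe sets, against 3.33 and 1.06 for independent lists, with none opposed. A probe set annotated only as uc022agz.1 had log2 signals of 4.10 and 4.26 on the vehicle arrays and 10.91 and 10.80 on the DHT arrays, and a second, uc003ora.2, of 6.29 and 5.89 against 10.16 and 10.45. Among those lower, uc003bpt.4 had 8.78 and 9.22 on the vehicle arrays and 5.38 and 5.74 on the DHT arrays. The lower level of each was below the floor of 6.82 and was not shown to lie above background, so no fold is given. These 3 were chosen after their values were seen.

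Known androgen targets were higher with DHT as a group. Of 53 genes listed as androgen-induced before the data were examined, 7 were measured, and 5 of these were 2-fold higher in both arms: SGK1, CENPN, IGF1R, LRIG1 and ZBTB16. The others, named after their values were seen, were the kallikrein gene KLK15, which differed by 0.31 and 0.04, and ADAM7, below the expression floor. The list median was 1.82 in siControl cells and 1.62 in siPOTEF-AS1 cells, both at the 100th percentile of 10000 matched random lists. The 3 measured genes of cholesterol synthesis and transport were higher in both arms. The list median was 0.65 in siControl cells, at the 99.7th percentile, and 0.81 in siPOTEF-AS1 cells, at the 99.9th. NSDHL, a sterol dehydrogenase gene, was higher by 0.66 and 0.81, the lanosterol demethylase gene CYP51A1 by 0.65 and 0.72, and STARD4, which encodes a sterol transfer protein, by 0.39 and 0.90. None of them reached 2-fold in either arm. The POTE median was 0.59 and 0.92, at the 99.95th and 99.96th percentiles, over copies that may read each other's transcripts. The 3 measured immediate early genes were not shifted as a list. NR4A1 was 1.43 and 1.12 higher, whereas JUN was 0.76 and 0.65 lower and CTGF (current symbol CCN2) differed by 0.00 and 0.23, for list percentiles of 53.2 and 91.9.

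The other lists had too few measured genes for a percentile. The endoplasmic reticulum chaperone cofactor genes MANF and DNAJB11 were higher with DHT by 0.78 ± 0.13 and 0.47 ± 0.04. TNFAIP3, an inhibitor of NF-kB signalling, was higher by 0.64 in siControl cells and by 1.14 in siPOTEF-AS1 cells, and the NF-kB target IER3 differed by -0.03 and 0.18. JUN was the only measured gene of 55 on the Toll-like receptor list, and BCL2, at -0.20 and -0.07, the only one of 10 anti-apoptotic genes. None of the 32 pro-apoptotic genes, the 17 androgen-repressed genes or the 28 genes of DNA replication was measured by name. The mitotic regulator CDC20 differed by -0.18 and -0.21 and the p53 target CCNG1 by -0.17 and -0.35. ATF4, SLC3A2 and the heat shock gene DNAJA1 each differed by less than 0.2 in either arm. KRT5, a basal keratin gene, differed by -0.04 and 0.49, and its siPOTEF-AS1 signals, 5.98 in vehicle and 6.47 in DHT, were below the floor. AKR1C1 and KRT15, named after their values were seen, were below the expression floor.

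**Figure D2:**
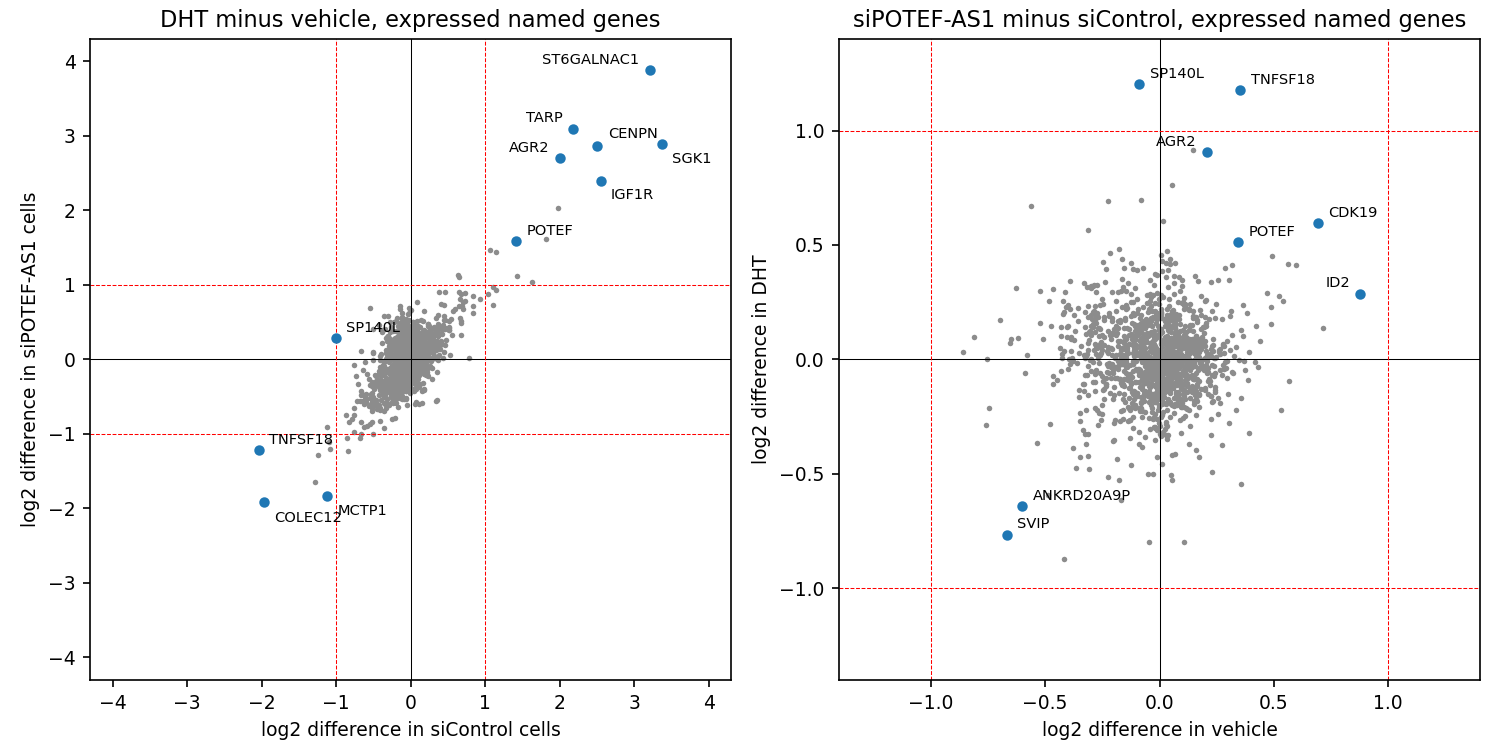
Log2 differences of 1344 expressed named genes, 1 point per gene, with DHT minus vehicle in siControl against siPOTEF-AS1 cells on the left and siPOTEF-AS1 minus siControl in vehicle against DHT on the right; dashed lines mark 2-fold. The DHT differences lie along the diagonal (r = 0.76), while the knockdown differences form a round cloud (r = 0.04) with no gene past 2-fold in both treatments.

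Knockdown differences were few and small. In vehicle, no expressed named gene was 2-fold different between siPOTEF-AS1 and siControl cells. In DHT, 2 were higher and none lower: SP140L, a gene of the SP140 nuclear body family, by 1.20 and TNFSF18 by 1.18. Both DHT values of TNFSF18, 5.31 and 6.49, were below the brightness floor, so that its difference lies between levels not shown to be above background, and only SP140L remained with a filter at the 75th percentile. Both pairs together gave 3 genes at 1.5-fold in the same direction. CDK19, a kinase gene of the Mediator complex (ENSG00000155111; chromosome 6, 110931181 to 111136519, minus strand, GRCh37), was higher by 0.69 in vehicle and by 0.59 in DHT, a mean of 0.64 ± 0.05 or 1.56-fold. SVIP, which encodes an inhibitor of endoplasmic reticulum-associated degradation, differed by -0.67 and -0.77, a mean of -0.72 ± 0.05 or 1.64-fold lower. ANKRD20A9P differed by -0.60 and -0.64. Its siPOTEF-AS1 DHT value, 6.11, was below the floor, so no fold is given. CDK19 and ANKRD20A9P fell short of 1.5-fold in one pair when arrays were centred on their medians or quantile-normalised again. In the linear model each of the 3 had a limma adjusted p of 0.32 for knockdown, the smallest value reached among the 1344 genes, so that 0 genes passed 0.05, and 62 had an unadjusted p under 0.05. Over annotated probe sets 0 of 13747 passed, and 784 had an unadjusted p under 0.05. If nothing had changed, a share of 0.05 would have such a p by chance. The gene count was below that share and the probe set count little above it, so neither count is a sign of a knockdown effect. Across the 1344 genes the knockdown differences of both treatments correlated with r = 0.04 (95% interval -0.03 to 0.10) and a Spearman rho of -0.02. This r depended on the brightness filter: it was -0.0866 without one and 0.2004 with the filter at the 75th percentile. Over the annotated probe sets r was 0.05. There, none was higher and 6 were lower at 2-fold in vehicle, 8 were higher and 1 lower in DHT, and no probe set was shared. At 1.5-fold 44 were higher and 71 lower in vehicle, and 70 higher and 69 lower in DHT. With arrays centred on their medians the 6 lower probe sets in vehicle became 1 higher and 4 lower. The robust SD of the knockdown difference over named genes was 0.16 in vehicle and 0.15 in DHT, against 0.20 and 0.30 for the DHT difference in siControl and siPOTEF-AS1 cells.

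Centring the arrays on their medians moved the knockdown difference of every named gene, and so each list median below, by 0.07 in vehicle and by -0.05 in DHT, and left the percentiles as they were. Of the gene lists, the interferon-stimulated genes were higher with knockdown in DHT. All 6 measured members of 33 were higher, BST2 by 0.76, CMPK2 by 0.60, OASL by 0.19 and IFI44L by 0.14, for a median of 0.17 at the 99.92nd percentile. Against random lists not matched on signal the percentile was 96.3, inside the central 95%. In vehicle 3 members were higher and 3 lower, with a median of -0.02 at the 29.9th percentile, and that median became 0.05 with arrays centred on their medians. The 3 cholesterol genes had a median of 0.25 with knockdown in DHT, at the 99.7th percentile, and of 0.10 in vehicle, at the 89.9th, or 0.17 after centring. Without matching on signal the value in DHT was inside the central range, at the 96.6th percentile. The androgen-induced list was inside the central range, with medians of 0.11 in vehicle and -0.11 in DHT at the 96.4th and 6.05th percentiles, or 0.18 and -0.16 after centring. The immediate early list was at the 91.2nd and 87.1st percentiles. JUN was higher by 0.29 in vehicle and by 0.40 in DHT, and BCL2 by 0.00 and 0.13. TNFAIP3 differed by -0.40 and 0.10 and KRT5 by -0.59 and -0.06. The BCL2 signals were at or below the brightness floor, and those of KRT5 below it in siPOTEF-AS1 cells.

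The comparison closest to the stated aim was that of the DHT responses of both siRNA arms. The response differed by 2-fold or more in 2 of 1344 expressed named genes, both higher with siPOTEF-AS1. SP140L (ENSG00000185404; chromosome 2, 231191899 to 231265339, plus strand, GRCh37) was 1.00 lower with DHT in siControl cells and 0.29 higher in siPOTEF-AS1 cells, a difference of 1.29. Its log2 signal was 8.26, 8.17 and 8.46 on the siControl vehicle, siPOTEF-AS1 vehicle and siPOTEF-AS1 DHT arrays and 7.25 on the siControl DHT array. The uncharacterised LOC100996378 differed by -0.54 and 0.69 with DHT, a difference of 1.23. The split of 2 higher and 0 lower became 2 and 2 with arrays centred on their medians, and 2 and 1 with the intensity trend removed or with quantile normalization. Over annotated probe sets 24 responses were higher and 8 lower with siPOTEF-AS1, and 16 and 15 after centring on the medians. Centring moved the median of this difference over all named genes by -0.12, more than it moved any single comparison.

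The interferon-stimulated genes also differed between the DHT responses. In siControl cells all 6 members were lower with DHT, or 5 of 6 with the intensity trend removed or with quantile normalization, with a median of -0.27 at the 1.41st percentile. In siPOTEF-AS1 cells 4 were higher and 2 lower, with a median of 0.05 at the 89.7th percentile that became -0.02 with arrays centred on their medians, 0.13 with the intensity trend removed, where 6 of 6 were higher, and 0.11 with quantile normalization. The difference of the responses was positive for 6 of 6 members, or 5 of 6 after that centring, with a median of 0.40, or 0.27 after centring, at the 100th percentile. BST2, which encodes tetherin, had the largest at 0.70 and CMPK2 the next at 0.59, and no member reached 2-fold. The siControl DHT array entered the DHT comparison of siControl cells, the knockdown comparison in DHT and this difference, so that these 3 values are not independent. The androgen-induced list had a lower response with siPOTEF-AS1, by a median of -0.20 at the 1.13th percentile, with 5 of 7 members lower, of which ADAM7 was far below the floor. Over the 6 expressed members, a choice made after seeing the data, the median was -0.18, at the 2.21st percentile with 4 lower. Centring the arrays moved the median of the 7 to -0.32. SGK1 differed by -0.48 and CENPN by 0.36. That shift was inside the central range without matching on signal, at the 2.58th percentile, with the intensity trend removed, at the 2.90th, and over the 5 members left by a filter at the 75th percentile, at the 5.65th. The POTE, cholesterol and immediate early lists lay at the 92.9th, 93.2nd and 81.5th percentiles.

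**Figure D3:**
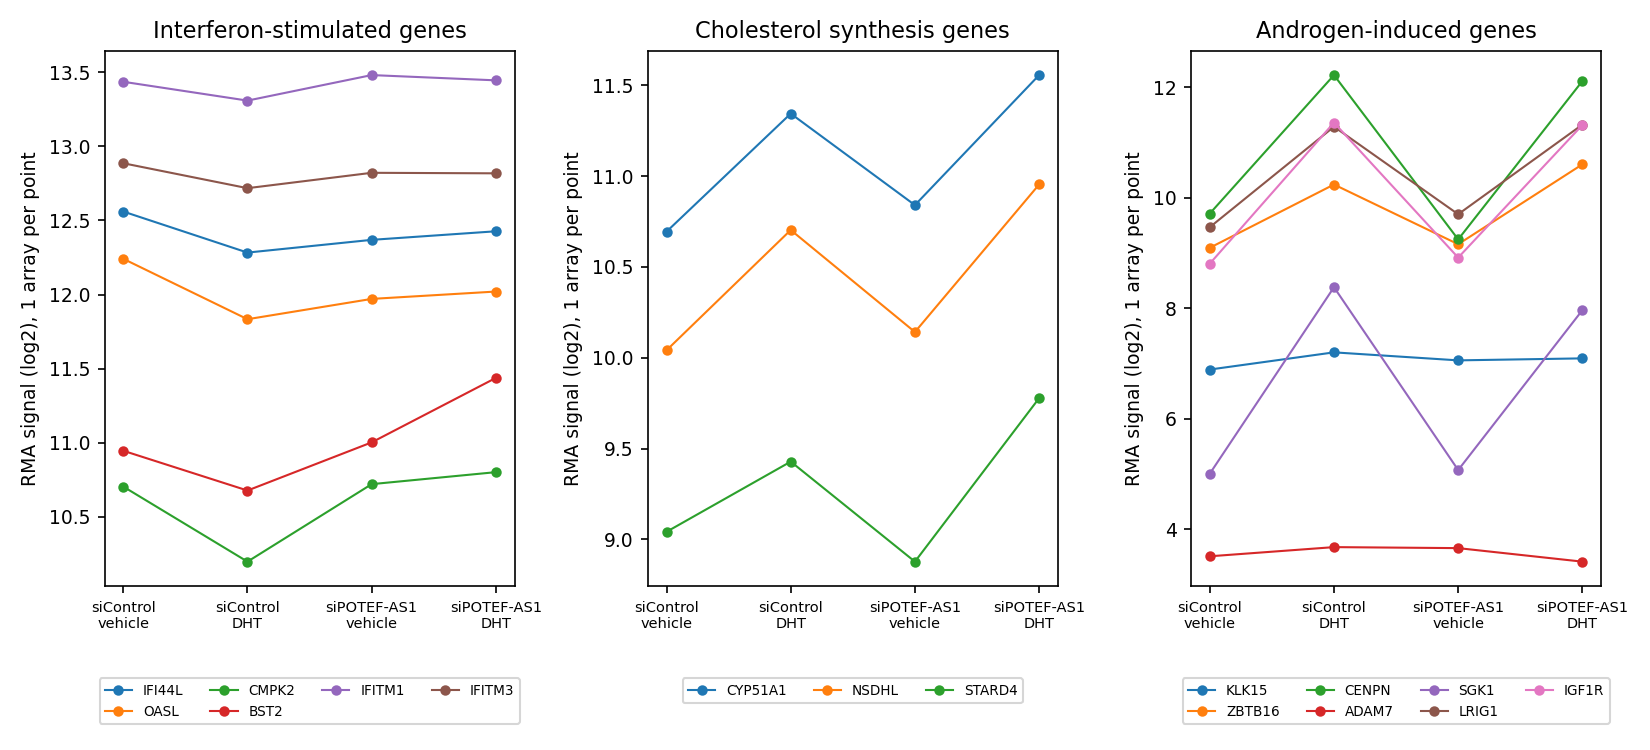
Log2 signal of each measured member of 3 gene lists, 1 point per array, joined by lines for each gene, with the 4 groups along the horizontal axis and a vertical axis of its own in each panel. Each of the 6 interferon-stimulated genes was lowest on the siControl DHT array, the 3 cholesterol genes were higher on both DHT arrays, and 5 of the 7 androgen-induced genes were at least 2-fold higher there in both arms.

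The size of the DHT response under knockdown depended on the arm in which responding genes were chosen. Among the 26 named genes at least 2-fold different in siControl cells, the response was larger with siPOTEF-AS1 in 13 and smaller in 13, with a median difference of -0.03 in the direction of the response. Among the 27 chosen in siPOTEF-AS1 cells it was larger in 20 and smaller in 7, with a median difference of 0.30. Over annotated probe sets it was smaller in 201 of 315 chosen in siControl cells and larger in 248 of 364 chosen in siPOTEF-AS1 cells. Each choice favours the arm used for it.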

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

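With 1 array per group no difference between groups in this part was tested. For the interferon genes, the vehicle comparison and the ranking of arrays were chosen after the result was seen, as were the class comparison of small RNAs and the tests on POTEF; the tests of an intensity trend and of signal brightness were not.

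The DHT response ran in opposite directions in the siRNA arms for SP140L, where the arms differed by 1.29 on the log2 scale, and for LOC100996378, where they differed by 1.23. The medians of the interferon-stimulated genes also had opposite signs, with a median of the member-wise differences of 0.40. That of siPOTEF-AS1 cells, 0.05 at the 89.7th percentile, was inside the range of random lists, 2 of the 6 members were lower in both arms, and the median became -0.02, with 4 of 6 members lower, with arrays centred on their medians. It rose to 0.133 with the intensity trend removed, with 6 of 6 higher, and to 0.115 with quantile normalization, with 5 higher and none lower. These differences were not tested. The probe sets with no annotated transcript had entered the correlations between arrays but none of the comparisons of groups. Of these, 12 were at least 2-fold different with DHT in the same direction in both arms, 8 higher and 4 lower. That compares with 0.67 for independent lists, and 3 were in opposite directions. Over the 3548 past their own median signal, the DHT differences of both arms correlated with r = 0.21, against 0.80 over annotated probe sets.

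The 6 interferon-stimulated genes were higher with knockdown in DHT, by a median of 0.17. Removing a smooth intensity trend between both DHT arrays left the median at 0.16, so such a trend accounted for little of the shift. The percentile of 99.88 after removal was no check, since random lists matched on signal carry most of such a trend too. An interferon response to siPOTEF-AS1 beyond that to siControl, regardless of hormone, would have raised the genes in vehicle too. The vehicle median was -0.0239, below the range of 0.12 to 0.68 that resampling the members gave for the median in DHT. Resampling members holds no variation between cultures or arrays, so it cannot set the vehicle and DHT comparisons apart. A response common to both siRNAs would not show in either comparison. All 6 members were lowest on the siControl DHT array, which in large part restates the comparisons that share this array. A lower interferon tone in control cells with DHT and a property of that single culture or array cannot be told apart, because the group and the array are the same. A DHT effect on interferon genes that is lost under knockdown stays a hypothesis that needs replicate cultures.

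Small noncoding RNAs had a higher DHT response with siPOTEF-AS1. Over 382 expressed probe sets the median difference of responses was 0.23, and 290 were higher, while these RNAs made up 2.78% of the expressed annotated probe sets, 6 of the 24 with a 2-fold higher response and 1 of the 8 with a 2-fold lower one. Probe sets of related small RNAs may not be independent measurements, so the counts and random ranges may overstate the shift. Their medians were -0.15 with knockdown in vehicle and 0.06 with knockdown in DHT. Each of 4 classes (ribosomal, miscellaneous, small nuclear and small nucleolar RNA) lay above its random range, the lowest at 0.14, which is consistent with a difference between arrays in the recovery of small RNAs during extraction or labelling. The brighter small noncoding probe sets had a median of 0.24, above their random range, so the shift was not confined to the dimmer ones. Brightness was ranked among these probe sets alone and signal over background was not known, so signal close to background is not excluded. A cellular difference in small RNAs stays open and untested.

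POTEF was 0.51 higher with knockdown in DHT, although its antisense transcript was the target. A stronger androgen response of all induced probe sets did not account for this, since the median knockdown difference of the 202 induced probe sets in DHT was -0.0109 (95% interval -0.05 to 0.03). The value was at the 94.1st percentile of those probe sets, inside their central range of -0.59 to 0.67, and may thus be part of the spread of induced genes between these arrays. Among all 13747 expressed probe sets it was at the 99.2nd percentile, and in vehicle, where POTEF was 0.34 higher, at the 97.3rd, or the 87.1st among the induced. The POTEF, POTEG, POTEB2 or POTEB and dimmer POTEI probe sets had knockdown differences in DHT within 0.12 of each other. In vehicle these differences lay within 0.32, and the pair SD was 0.14. The POTEB2 or POTEB probe set was below the brightness floor of named genes on every array, at 5.02 to 6.20. POTEG was below it on both vehicle arrays, and POTEF and the dimmer POTEI on the siControl vehicle array. Differences at such levels may be compressed, so the vehicle spread cannot bear on the cause. Common reading of near-identical copies and a difference of these genes cannot be told apart without probe sequences. POTEJ differed by 0.264 and the brighter POTEI probe set by -0.072 with knockdown in DHT, so that the 6 POTE probe sets did not move alike. A rise of POTEF on loss of its antisense RNA is a hypothesis that these arrays do not settle.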

How the results depend on the processing

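The repeats on annotated probe sets, the linear model, the lists of expressed members alone, the removal of small noncoding RNAs and the separate counting of identical probe sets were chosen after seeing the data. The second deposited table held the same values. Under the 3 other scalings 67 of 72 values of single named genes kept their direction and their side of the threshold, and the other 5 (ID2, and CDK19 and ANKRD20A9P under 2 scalings each) kept their direction but fell short of it in an arm. The other settings changed no such value, the filters and the second table by construction. The mean of all probe sets of a gene moved none of the 24 values, so it was no check on them. The filter on the mean of 4 arrays removed MCTP1, and that at the 75th percentile removed 8 of the 24 values, those of POTEF, TNFSF18, MCTP1, RFX3, C10orf91, LOC100996378 and ANKRD20A9P (2 values). Other scalings moved the median difference of all genes by at most 0.12. Signal over background is unknown for single probe sets.

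In place of the 2-fold rule in both pairs, the limma fit of siRNA and hormone, which assumes that the effects add, gave 112 named genes for DHT at an adjusted p under 0.05, 51 higher and 61 lower, and 1994 annotated probe sets, 909 higher and 1085 lower. Of these, 24 genes and 309 probe sets were 2-fold apart. A test of change does not ask for a fold, so the counts differ by construction. For knockdown it gave 0 of each, with 62 genes and 784 probe sets at an unadjusted p under 0.05. Both counts are near the share of 0.05 that chance alone would give.

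The fold threshold and the filter set the counts by construction. At 1.5-fold, 3-fold and 3 robust SDs the counts of named genes were 79, 11 and 70 for DHT in siControl cells, 103, 12 and 51 for DHT in siPOTEF-AS1 cells, 17, 0 and 34 for knockdown in DHT, 55, 0 and 27 for the difference of the responses, and 55, 9 and 43 for both DHT pairs. Knockdown in vehicle gave 17 at 1.5-fold and 38 at 3 robust SDs, and both knockdown pairs 3 and 7. Over annotated probe sets these counts were 995, 103 and 837, then 1295, 95 and 625 for DHT, 115, 0 and 332 for knockdown in vehicle, 139, 0 and 320 for knockdown in DHT, 425, 2 and 248 for the difference of the responses, and 702, 74 and 482 for both DHT pairs. Both knockdown pairs gave 14 at 1.5-fold and 65 at 3 robust SDs.

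Without a filter on dim genes, 4 named genes were 2-fold different with knockdown in vehicle, 7 with knockdown in DHT and 22 in the difference of the responses, and 34, 38 and 156 annotated probe sets. The correlation of both pairs was then 0.539 for DHT and -0.0866 for knockdown over named genes, and 0.603 and -0.0465 over annotated probe sets. With the highest array above the 75th percentile the counts were 16 for DHT in siPOTEF-AS1 cells, 1 for knockdown in DHT, 1 for the difference of the responses and 13 for both DHT pairs, and 231, 3, 4 and 9 annotated probe sets for DHT in siPOTEF-AS1 cells, knockdown in vehicle, knockdown in DHT and the difference. The correlations were 0.872 and 0.2004, and 0.890 and 0.223. Centring the arrays on 1 median gave 4 named genes in the difference of the responses. Without small noncoding RNA probe sets, which also raised the brightness floor, 3 probe sets differed with knockdown in vehicle and 20 in the difference of the responses, and the correlations were 0.832 for DHT and 0.116 for knockdown.

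The median change of the DHT response under knockdown turned from -0.03 to 0.301 in named genes, and from -0.14 to 0.173 in annotated probe sets, when genes were chosen by the siPOTEF-AS1 arm, as choosing by either arm must favour it. It was -0.197 in the androgen-induced list. Random lists not matched on signal put the androgen-induced list at the 2.58th percentile for the difference of the responses and the interferon list at the 96.33rd for knockdown in DHT, both inside the central range, and removing the intensity trend put the former at the 2.90th. With the highest array above the 75th percentile it stood at the 5.65th, over 5 members, and the POTE and immediate early lists had too few members left for a value. The cause was not tested for the lists.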

Other observations

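All the values in this part were chosen after the data were seen. Among Gene Ontology terms given in the deposited table, 10 had at least 10 expressed named genes, and their medians were set against matched random lists in 5 comparisons. Of these 50 medians 8 lay outside the central 95%, against 2.5 expected by chance. That expectation may be low, since 8% of unchanged simulated lists of 6 genes lay outside the range. The 8 medians came from 4 terms, and the comparisons share arrays, so the medians are not independent. The clearest was nucleosome assembly, whose 15 members were all histone genes. With DHT 15 of 15 were lower in siControl cells, with a median of -0.24 at the 0.13th percentile, and 14 of 15 in siPOTEF-AS1 cells, with a median of -0.32 at the 0.04th percentile. HIST1H2BF was lower in both arms, by a mean of -0.59 ± 0.04, HIST1H2AM by -0.52 ± 0.07 and HIST1H2AL by -0.50 ± 0.03. HIST1H2AL was below the brightness floor on both DHT arrays and on the siPOTEF-AS1 vehicle array. No member reached 2-fold, and histone genes of a cluster are near-identical copies whose probe sets may not be independent measurements.

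Genes of the mitotic cell cycle were lower with DHT in siPOTEF-AS1 cells, with a median of -0.29 at the 0.19th percentile over 14 genes, of which 10 were lower. In siControl cells 9 of 14 were lower, with a median of -0.09 at the 18.8th percentile, inside the random range, and with knockdown in DHT the median was -0.14 at the 0.50th percentile. RFC3, a subunit of the clamp loader of DNA replication, differed by -0.51 in siControl and by -1.01 in siPOTEF-AS1 cells, and the kinetochore gene SPC24 by -0.36 and -0.92. CENPN, which was higher with DHT in both arms, was also on this list. The median of the difference between the responses was -0.16, at the 0.54th percentile. Cell adhesion genes had a lower response with siPOTEF-AS1 by a median of -0.24, at the 0.06th percentile over 10 genes. The shift was carried by 4 protocadherins of the beta cluster, related genes whose probe sets may not be independent: the other 6 genes had a median of 0.03 at the 58.7th percentile, with 3 higher and 3 lower. PCDHB14 differed by 0.16 with DHT in siControl cells and by -0.59 in siPOTEF-AS1 cells, and PCDHB3 by 0.18 and -0.42. The term for nonsense-mediated decay held 12 genes, mostly of ribosomal proteins. Their median with DHT was -0.09 in siControl cells, at the 40.3rd percentile, and -0.21 in siPOTEF-AS1 cells, at the 1.45th, where 11 of 12 were lower. The median of the difference between the responses was -0.11, at the 1.15th percentile. These differences between arms rest on single arrays and were not tested.

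IFI16, an interferon-inducible gene that was not on the fixed list, was 0.92 higher with knockdown in DHT and 0.14 higher in vehicle. Its value in DHT uses the same siControl DHT array as the interferon list, so it is not independent of that list. Other interferon-inducible genes off the list are not given here.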
